A study of Anopheles gambiae with 6 samples.

How the data were processed

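Gene expression was measured in RNA of whole adult male Anopheles gambiae on Agilent two-colour mosquito arrays of the 4x44,000 format. Per the labels, the Cy3 channel held RNA of males treated with dsHSF1 or dsHSF123 and the Cy5 channel RNA of dsLacZ-treated males, with 3 arrays for each knockdown. The meaning of the number in dsHSF123 is not given in the sources used here.

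The deposited file of each array holds 1 processed signal intensity per probe and channel, and its header names the Cy5 column as control and the Cy3 column as signal. Per the submitters' processing notes these intensities came from Agilent Feature Extraction 9.5.3.1, and per the series design text the signals were normalised there by a linear and a loess step and passed to Genespring GX 11.0. Such a dye normalization assumes that most probes do not change at a given brightness, so a change shared by most transcripts would be removed from the ratios. Raw and background signals, spot quality marks and background marks were not used here. The authors' deposited value table holds log2 ratios. Set against the processed signals it equalled log2(Cy3/Cy5) on every array, with a largest difference of 4.74e-07, so its scale is log2, it is not centred, and positive values mean a higher level in the knockdown. Its column medians were −0.01, −0.09 and −0.10 for HSF1 replicates 1 to 3 and −0.07, −0.07 and −0.07 for HSF123 replicates 1 to 3.

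From the processed signals log2(Cy3/Cy5) was computed for 43603 mosquito probes, and 60 control probes were left out of the tests. No further normalization was applied in the main setting. The ratios were fitted with limma 3.58.1 (lmFit, contrasts.fit and eBayes, two-sided) in R 4.3.3, with a mean for each knockdown and 1 estimate of the spread from all 6 arrays. Each mean was tested against 0 and the means against each other. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold, the criteria in the series design text, which names a t-test of the log ratios against 0. A test against 0 leaves out the spread of the control RNA. Because the series design text calls the arrays of a knockdown technical replicates, p-values measure only the spread between hybridisations, and the number of arrays limits the precision. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

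The comparisons, tests, thresholds and the rule for naming genes were fixed before the data were examined. This plan kept all probes in the test where no background marks were given. After the data were seen, calls were also counted among probes above background, meaning a signal over 3 times the highest of 2 negative controls in both channels on all 3 arrays of a group, or of both groups for the contrast. The floor, 1 value for both channels of an array, was 44.1 on HSF1 replicate 1 and 23.3 to 26.2 on the other arrays. These counts are given first in each comparison. The planned rule named the largest changes with a product name and members of fixed gene lists. Because 0 probe identifiers matched a gene table, it was reduced to the 2 largest rises and 2 largest falls per comparison that passed the threshold, had the same sign on all 3 arrays (or in every pair of arrays for the contrast) and were above background. The fixed gene lists, the gene-level values and the check of HSF were not analysed here.

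The procedure was tested on simulated data with 43603 probes. For HSF1 knockdown against dsLacZ it recovered 72 of 100 probes changed 3-fold and 92 of 100 changed 6-fold, with 0 false calls. For the contrast it recovered 49 and 82 of 100, with 6 false calls, and unchanged HSF123 arrays gave 0 calls. The simulated noise was independent between arrays and centred on 0, without dye bias or a signal floor, so few false calls follow by construction. They do not give the rate of false calls in the real data, where 27 control probes had a median log2 ratio of −1.45 on the HSF123 arrays.

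Replicate numbers were checked as pairs. The file headers put arrays of the same number on the same slide, 1 of each knockdown, with a fixed position on the slide for each knockdown. Slide therefore pairs the arrays, and position on the slide cannot be told apart from knockdown. Deviations from the group means correlated at −0.01, −0.02 and 0.03 within slides 1, 2 and 3. The main fit used no block. In an alternative setting, slide was a fixed block for the contrast and a random block (duplicateCorrelation, consensus 0.0241) for the tests against 0.

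Alternative settings fixed before the data were examined were centring on the array median, quantile normalization, leaving out the lower quartile of intensity, the deposited ratio table, each group fitted alone, the methods' t-test, the adjusted p alone, the slide block and leaving out each array. Chosen after seeing the data were the background floor, with limits of 2 and 5 times the negative control, a fit of the probes above background alone, and centring on 10 E1A spike-in probes. The last was applied only to the contrast, because the amounts of spike-in added to the channels are not given in the sources used here.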

Results

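Adult Anopheles gambiae males were compared after RNA interference directed at HSF, which the labels name only by this abbreviation. RNA from males treated with double-stranded RNA (dsRNA) called dsHSF1, or with a second dsRNA called dsHSF123, was measured against RNA from males treated with dsLacZ, a dsRNA against a bacterial gene that served as control. Whole males 4 days old were used, and the series title places the work in the regulation of male accessory gland genes. Each of the 6 two-colour arrays carried knockdown RNA in the Cy3 channel and dsLacZ RNA in the Cy5 channel, with 3 arrays for HSF1 knockdown and 3 for HSF123 knockdown. The dyes were not swapped on any array. The series design text calls the 3 arrays of a knockdown technical replicates, so the errors and p-values given here measure the spread between hybridisations and not between groups of males.

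Each array reported 43663 probes, of which 43603 were mosquito probes and 60 were controls. Median signals were 296 in Cy5 and 289 in Cy3 on HSF1 replicate 1, and lay between 137 and 145 in both channels of the other 5 arrays. In both channels of all 3 arrays of a group, 28885 mosquito probes (66.2%) stood above background on the HSF1 arrays and 28503 (65.4%) on the HSF123 arrays, and 28067 (64.4%) did so on both sets. Above background means a signal over 3 times the highest negative control of the array, with 1 limit for both channels. On the HSF123 arrays, median signals of 12 RC control probes were 7.58 to 8.05 in Cy5 but 2.59 to 3.11 in Cy3. On HSF1 replicates 2 and 3 their Cy3 medians were 4.36 and 5.02. Relative to these control signals the limit was stricter in Cy3, most of all on the HSF123 arrays. Among those 28067 probes, log2 ratios of 2 arrays of the same knockdown correlated across probes at 0.90 to 0.94 when HSF1 replicate 1 was left out. Across knockdowns the correlation of the same arrays was 0.642 to 0.647. HSF1 replicate 1 correlated at 0.784 to 0.785 with the other HSF1 arrays and at 0.552 to 0.562 with the HSF123 arrays. The files do not pair the probes with genes, and no table used here does, so results are given by probe, with at most 2 probes named each way in a comparison. For the same reason the level of HSF itself was not analysed here.

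The comparison of HSF1 knockdown with dsLacZ asked which transcripts changed in males when HSF was targeted with the dsHSF1 reagent. Of the 28885 probes above background, 797 (2.76%) were at least 2-fold higher and 1306 (4.52%) at least 2-fold lower in HSF1 knockdown males, with median log2 ratios of 1.21 and −1.28. More than 4-fold changes were seen for 21 probes that rose and 90 that fell. Among these, the largest rise was that of probe A_90_P059291, with a log2 ratio of 3.12 ± 0.06 (SD, n = 3 arrays), an 8.69-fold increase (limma adjusted p = 3.73e-05). Probe A_90_P044798 followed at 3.03 ± 0.29 (8.17-fold, limma adjusted p = 6.43e-05). The largest falls were those of A_90_P050714, at −3.04 ± 0.04 (8.21-fold, limma adjusted p = 3.07e-05), and A_90_P050930, at −2.95 ± 0.01 (7.73-fold, limma adjusted p = 3.07e-05). All 4 probes changed in the same direction in HSF123 knockdown males, by less: 2.19 ± 0.24, 2.19 ± 0.17, −1.17 ± 0.02 and −1.29 ± 0.05. The difference between the knockdowns had limma adjusted p-values of 0.00953, 0.0241, 0.000932 and 0.00110 for these probes.

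Over all 43603 probes the test called 1280 higher and 1739 lower. Of these, 352 higher and 139 lower probes were above background on all 3 arrays in 1 channel only, and 131 and 294 in neither channel. Quantile normalization of the ratios of all probes, dim ones included, changed the numbers above background to 758 higher and 2158 lower. Leaving out HSF1 replicate 1 gave 939 and 1666. Centring each array on its median ratio gave 974 higher and 1101 lower above background, and turned the balance over all probes to 1534 higher and 1425 lower. Because the dyes were not swapped, a bias of a probe towards either dye, or a peculiarity of the dsLacZ RNA, is part of each of these ratios.

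The same question was put for the dsHSF123 reagent. Of 28503 probes above background, 455 (1.60%) were at least 2-fold higher and 455 (1.60%) at least 2-fold lower in HSF123 knockdown males, with median log2 ratios of 1.24 and −1.17. More than 4-fold changes were seen for 25 probes that rose and 19 that fell. Among these, probe A_90_P079406 rose most, by 3.1 ± 0.14 on the log2 scale (SD, n = 3 arrays; 8.59-fold, limma adjusted p = 0.000114), while its ratio in HSF1 knockdown males was −0.07 ± 0.09 (limma adjusted p = 0.433). A_90_P032550 came next at 2.89 ± 0.33 (7.43-fold, limma adjusted p = 0.00379). Its control signal averaged 34.5, close to the background limits of up to 26.2 on these arrays. In HSF1 knockdown males this probe gave 1.84 ± 1.17, with array values of 0.55, 2.13 and 2.84, and the difference between the knockdowns was 1.05 (95% interval −0.49 to 2.60, limma adjusted p = 0.261). The largest falls among the probes above background were those of A_90_P076991, at −3.81 ± 0.09 (14.01-fold, limma adjusted p = 0.000114), and A_90_P076995, at −3.65 ± 0.08 (12.6-fold, limma adjusted p = 0.000114). These 2 probes also fell in HSF1 knockdown males, to −1.40 ± 0.22 and −1.16 ± 0.22, and the fall was larger in HSF123 knockdown (limma adjusted p = 0.00129 for each difference). A probe that falls to background in the knockdown is left out of this ranking. One such probe, A_90_P000517, had a ratio of −4.44 (limma adjusted p = 0.000146) but was not above background in both channels on the HSF123 arrays.

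Over all 43603 probes, 1085 were called higher and 6154 lower, but 5609 of the latter (91.1%) were above background in neither channel. Above background in 1 channel only were 320 higher and 90 lower probes, and 310 higher probes were above it in neither. The median log2 ratio of 27 control probes was −1.45 on the HSF123 arrays, where the ETG probes among them were all below the floor in Cy5, and 99.2% of those 5609 probes lay within 0.5 of the HSF123 value. The balance of rises and falls above background depended on the scaling: centring each array on its median ratio gave 583 higher and 334 lower, and quantile normalization 522 and 187. Quantile normalization gave the arrays 1 distribution of ratios over all 43603 probes, dim probes included. The 27 control probes had median ratios of −1.45 on the HSF123 and −0.52 on the HSF1 arrays. Quantile-normalized counts may carry that difference between the groups.

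**Figure D1:**
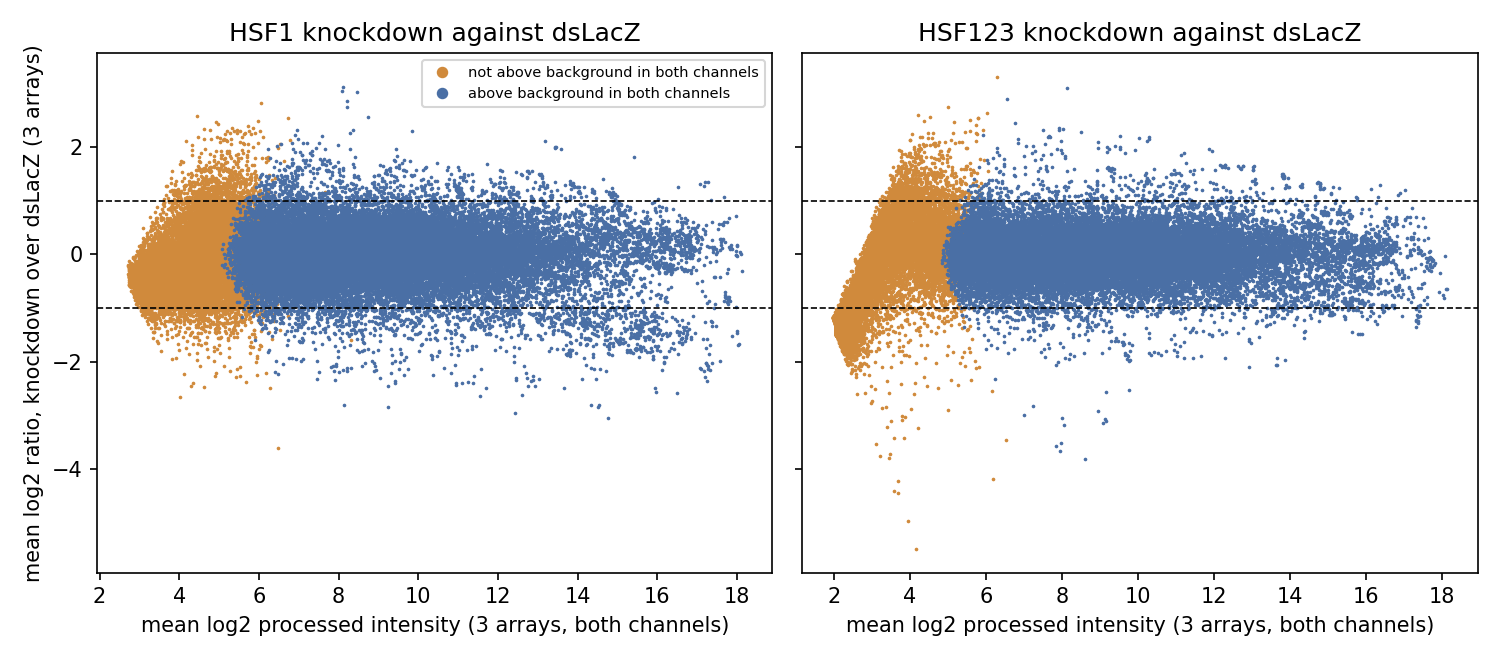
Each point is 1 mosquito probe, with its mean log2 ratio of knockdown over dsLacZ (3 arrays) on the vertical axis and its mean log2 processed intensity over both channels on the horizontal axis, for HSF1 knockdown on the left and HSF123 knockdown on the right. Blue probes were above background in both channels on all 3 arrays, orange probes were not, dashed lines mark 2-fold changes, and the 5609 dim probes called lower in HSF123 knockdown lie at the lower left of the right panel.

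The contrast of HSF123 with HSF1 knockdown compared the reagents with each other. A probe's dye bias cancels in this difference of ratios only as far as it was equal on both sets of arrays, and the median ratio of the 27 control probes was −0.17, −0.76 and −0.64 on HSF1 replicates 1, 2 and 3 but −1.59, −1.41 and −1.37 on the HSF123 arrays. On HSF1 replicate 1, 10 of the 13 ETG probes among them exceeded the floor in Cy5. Of the 28067 probes above background in both groups, 442 (1.57%) were at least 2-fold higher and 275 (0.980%) at least 2-fold lower in HSF123 than in HSF1 knockdown males. Among these, the probe with the largest positive difference was A_90_P079406, at 3.18 on the log2 scale (SE 0.10, 3 arrays per group; 9.03-fold, limma adjusted p = 0.000932). It was followed by A_90_P036442, at 2.29 (SE 0.07; 4.90-fold, limma adjusted p = 0.000932), which had fallen in HSF1 knockdown (−2.35 ± 0.09) and had a ratio of −0.05 ± 0.02 in HSF123 knockdown (limma adjusted p = 0.419). The largest negative differences among the probes above background were those of A_90_P085300, at −3.38 (SE 0.06; 10.4-fold, limma adjusted p = 0.000307), and A_90_P085298, at −3.15 (SE 0.07; 8.85-fold, limma adjusted p = 0.000308). Both probes moved in opposite directions in the knockdowns. A_90_P085300 rose to 1.56 ± 0.02 in HSF1 and fell to −1.82 ± 0.02 in HSF123 knockdown males, and A_90_P085298 rose to 1.21 ± 0.04 and fell to −1.94 ± 0.07. Probes above background in 1 group only were not ranked, among them A_90_P000517, with a difference of −5.125 (limma adjusted p = 0.00147).

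**Figure D2:**
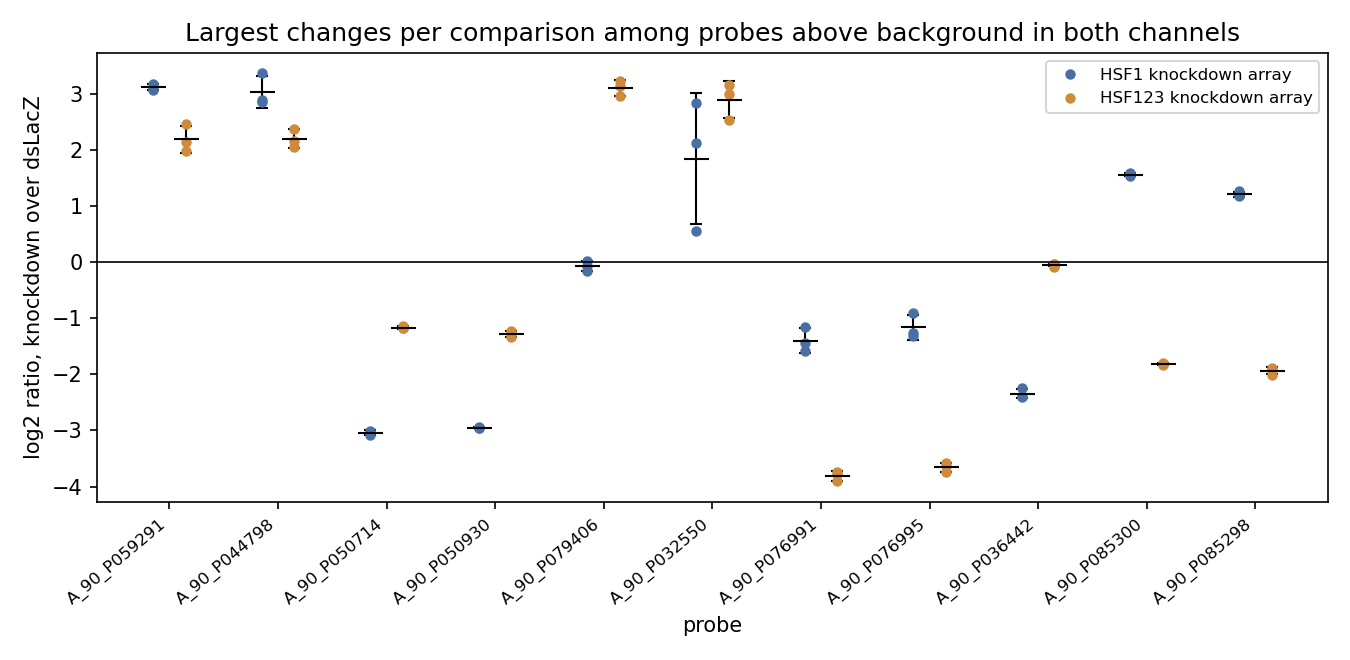
Each point is the log2 ratio of knockdown over dsLacZ on 1 array (vertical axis) for the 11 probes with the largest changes among those above background in both channels (horizontal axis), with HSF1 arrays in blue and HSF123 arrays in orange; horizontal bars are means and error bars SDs of 3 arrays. A_90_P085300 and A_90_P085298 lie above 0 on every HSF1 array and below 0 on every HSF123 array.

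Over all 43603 probes, 671 were higher and 1254 lower in HSF123 than in HSF1 knockdown males, and 932 of the latter (74.3%) were above background in neither channel in at least 1 group. A further 55 higher and 47 lower probes had at least 1 channel above background in each group but not both channels in both. The arrays came from 3 slides, each with 1 array of either knockdown. With the slide as a block, 437 probes were higher and 354 lower, a total of 791 against 1925, and above background 341 were higher and 225 lower. Within slides 1, 2 and 3, differences of at least 2-fold above background were positive for 789, 794 and 785 probes and negative for 487, 448 and 471, with no test. Centring each array on its median ratio gave 451 higher and 272 lower above background, close to the main split. Quantile normalization, dim probes included, gave 798 and 213. Over all probes the balance turned to 1063 higher and 400 lower with quantile normalization, 959 and 839 without HSF1 replicate 1, and 515 and 433 without HSF123 replicate 1. Centring each array on the median of its 10 E1A spike-in probes moved the median difference above background from −0.02 to 1.43, and then 25164 probes were higher and 9 lower above background (31662 and 20 of all probes). Under that scaling A_90_P085300 and A_90_P085298 were still lower, with differences of −1.93 and −1.69.

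The responses to both reagents were then set side by side over the 28067 probes above background on all arrays. There 2062 probes passed the threshold in HSF1 knockdown and 896 in HSF123 knockdown. In both knockdowns 206 probes rose and 235 fell, where independent lists of these lengths would share 12 and 20.9. A further 10 probes rose in HSF1 and fell in HSF123 knockdown, against 12.2 for independent lists, and 0 fell in HSF1 and rose in HSF123 knockdown, against 20.7. The shared rises and falls show that the lists were not independent, so these values set no chance level for the 10 probes. All 10 also passed the limma test of the difference between the knockdowns, which opposite calls of at least 2-fold made all but certain. A_90_P085300 and A_90_P085298 were among the 10. Of the 10 probes, 8 lay in 2 runs of consecutive probe numbers. Of the probes called in HSF1 knockdown, 1970 (95.5%) had the same sign in HSF123 knockdown, and of those called in HSF123 knockdown, 855 (95.4%) had the same sign in HSF1 knockdown. The 758 probes that rose in HSF1 knockdown had a median log2 ratio of 1.21 there and 0.71 in HSF123 knockdown, and the 1304 that fell had medians of −1.28 and −0.64. Chosen the other way, the 446 probes that rose in HSF123 knockdown had medians of 0.97 in HSF1 and 1.24 in HSF123 knockdown, and the 450 that fell −1.03 and −1.17, so each selection gave the larger median in the knockdown used to select. Of 1611 probes past the threshold in HSF1 knockdown alone, 354 were also called in the contrast, and of 445 past it in HSF123 knockdown alone, 58 were. A call in the contrast needs a limma adjusted p under 0.05 and a difference of at least 2-fold, so smaller differences are not counted.

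Across the 28067 probes, which are not independent replicates, the ratios of the knockdowns correlated at 0.676 with a covariance of 0.163, and 74.1% of probes had the same sign. In 20 simulations with unchanged groups and independent hybridisation noise, the mean correlation was −0.00331, the mean covariance −4.29e-05, the mean share of equal signs 50.05%, and the highest number of probes called in both 0. Values near these follow from unchanged groups with independent noise by construction. The simulations contain neither the dye bias nor what the dsLacZ RNA of the arrays had in common, and the control RNA could not be split, so part of the observed correlation and overlap may come from them.

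**Figure D3:**
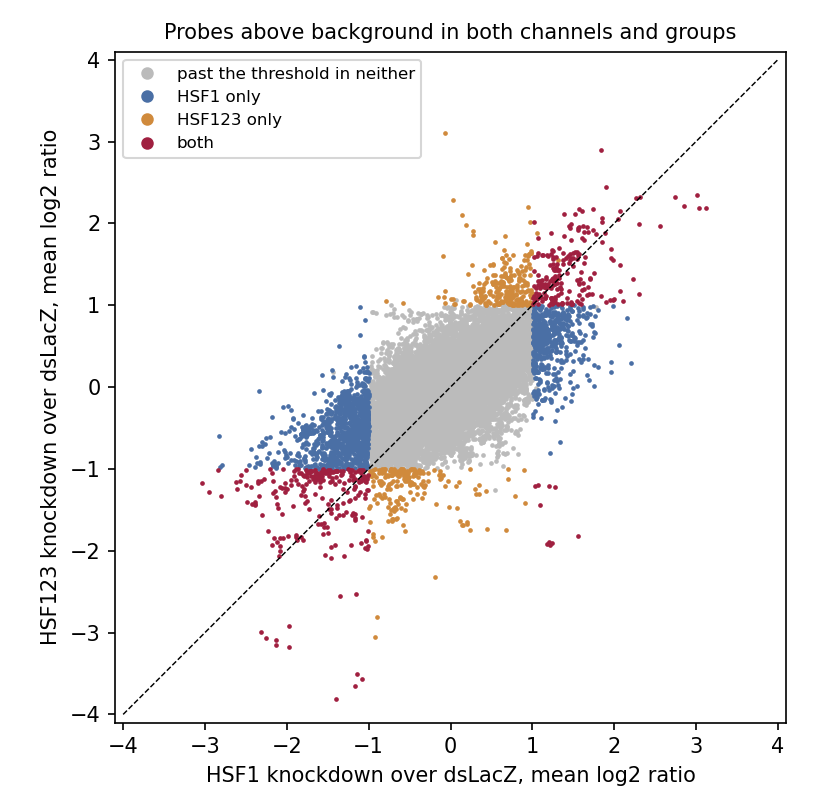
Each point is 1 of the 28067 probes above background in both channels and both groups, with its mean log2 ratio over dsLacZ in HSF1 knockdown (horizontal axis, 3 arrays) and in HSF123 knockdown (vertical axis, 3 arrays), coloured by the knockdowns in which it passed the threshold. The dashed line marks equal ratios, and the 10 red probes at the lower right rose in HSF1 and fell in HSF123 knockdown males.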

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

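The tests on the ETG and RC control probes of HSF1 replicate 1, on consecutive probe numbers and on the spike-ins were chosen after the results were seen, and the correlation of bright probes was fixed before.

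A group of 10 probes changed in opposite directions in the knockdowns and drew attention because the groups differed. Each was at least 2-fold higher in HSF1 and at least 2-fold lower in HSF123 knockdown males. Each passed the limma test of the difference, but this choice of probes made that all but certain, so it adds no support. Independent lists of the same lengths would share 12.2 such probes. The lists were far from independent (206 shared rises against 12), so that value sets no chance level for the 10. The 10 probes form 4 runs of consecutive numbers, with 8 probes in 2 of the runs. They may match as few as 4 transcripts if consecutive probes share one (correlation of 0.804 over such pairs). They included A_90_P085300, at 1.56 ± 0.02 against −1.82 ± 0.02 on the log2 scale (SD, n = 3 arrays each).

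On HSF1 replicate 1, 10 of 13 ETG control probes, which the report's comparisons did not use, exceeded the background floor in Cy5, against 0 on each of the other 5 arrays. Mosquito probes showed the same thing: of 10303 at or below the floor on the other arrays, 6535 (63.4%) were above it in both channels here, with a median Cy5 signal of 71.6. The excess in log2 intensity over HSF1 replicates 2 and 3 reached brighter probes, classed by mean log2 intensity on the other arrays. Its median was 0.68 for 7648 probes of 6 to 8, 0.17 for 8094 of 8 to 10 and 0.0009 for 5702 of 10 to 12. At 6 to 8 the SD of the ratios was 0.52 on this array, against 0.63 and 0.64 on replicates 2 and 3. Counts above background therefore include affected probes. A full exchange of the RNA sample is argued against, but a small share of another RNA is not, by the log2 ratios of 10256 bright probes, which correlated at 0.965 with HSF1 replicate 2 and 0.968 with replicate 3, against 0.720 to 0.724 with the HSF123 arrays. A uniform background offset is argued against by the RC control probes, whose median Cy5 signal was 11.7, or 0.163 of the dim mosquito probes' median. Hybridisation that was not specific to the target may account for the extra signal but stays open, since the ETG probes are what drew attention to the array, and no biological explanation was tested.

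The 10 E1A spike-in probes, also unused in the comparisons, had a log2 ratio lower by a mean of −1.36 on the HSF123 than on the HSF1 arrays (SD 0.21 over the probes). Their mean log2 signal shifted by −1.68 in Cy3, the knockdown channel. In Cy5 it shifted the same way, by −0.32, which offset part of the Cy3 shift in the ratio. The intensity-dependent part of the dye normalization stays open, because the median difference of −0.0305 over 18618 mosquito probes of the spike-ins' brightness is held near 0 by that normalization. A smaller amount of spike-in in the HSF123 labelling and a larger amount of labelled mosquito RNA in HSF123 knockdown males could both give such a shift, and with an SD of 0.210 between spike-ins the data do not separate these. A biological difference between the knockdowns in total RNA stays open and was not tested further.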

How the results depend on the processing

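Counts above background, the floors of 2 and 5 times the negative control, the fit of those probes alone, the spike-in centring and the quantile-normalized values of the named probes were chosen after seeing the data, and the other settings were planned. Of the alternative values of the counts, 132 stayed within 1.5 times the main count and 26 moved further. Only totals are compared in this, not which probes were called. In the contrast, the main calls held 1093 of 1798 probes called without HSF1 replicate 1. They held 1036 of 1463 called with quantile normalization and 1888 of 2074 called with median centring. The 132 include the deposited ratio table, which equals the main ratios, so its counts had to repeat. Of the alternative values of the named probes, 100 of 100 kept their direction and call, which shows little. These probes were chosen as the largest called changes with the same sign on every array or pair of arrays. Leaving out an array of the other knockdown could not change a ratio against dsLacZ. The t-test, the slide block and the separate fits gave no values for the named probes. Dim probes added many calls. Without the lower quartile of intensity, 1476 probes (906 higher, 570 lower) were called for HSF123 knockdown and 936 (588 and 348) for the contrast, since fewer dim probes were tested. Elsewhere the cause was not tested. Quantile normalization, which took in the dim probes, gave 2158 lower for HSF1, 187 lower for HSF123 and 798 higher in the contrast above background. The methods' t-test against 0 with Benjamini-Hochberg adjustment called 1473 probes for HSF1 (520 higher above background) and 293 in the same direction in both knockdowns. For the contrast a t-test between the groups with pooled variance stood in for it and called 1145. At an unadjusted p under 0.05 and 2-fold these t-tests gave 887 higher and 1359 lower for HSF1, 920 and 5530 for HSF123, and 763 and 1614 for the contrast.

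The adjusted p alone, a looser criterion, gave 21122, 21478 and 11668 probes for HSF1, HSF123 and the contrast, 9664 shared, and above background 8760 higher and 7932 lower, 6914 and 7086, and 3972 and 4033. The slide, which pairs the arrays, as a replicate block gave 791 in the contrast and changed no other count by over 1.5 times (3018 for HSF1, 7240 for HSF123). Spike-in centring gave 31682 in the contrast, and above background 25164 higher and 9 lower. Leaving out each array gave 948 to 2181 in the contrast, with 948, 1163 and 1056 without HSF123 replicates 1, 2 and 3. Above background the ranges were 371 to 645 higher and 245 to 317 lower. Without HSF1 replicate 1, HSF1 calls above background numbered 939 higher and 1666 lower, of which 729 and 1291 were among the main calls. Normexp on raw signals, probes averaged per gene and camera were not run, and no dim-probe filter was in place to remove.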

Other observations

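The tests on the dim probes called lower and on probes with consecutive numbers, and the brightness classes, were chosen after the results were seen. The splits of the arrays were fixed before.

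The brightest probes fell most often in HSF1 knockdown males. Of 1747 probes above background with a mean log2 intensity over 14, 409 (23.4%) were at least 2-fold lower and 36 higher in HSF1 knockdown, against 65 lower (3.72%) and 33 higher in HSF123 knockdown. Of 9717 probes under 8, 238 (2.45%) were lower in HSF1 knockdown. Within the class the log2 ratios had an SD over probes of 0.80 in HSF1 and 0.51 in HSF123 knockdown, and a shift of the whole class would be removed by the dye normalization. The 409 probes, chosen by their HSF1 ratios, had median ratios of −1.42 in HSF1 and −0.68 in HSF123 knockdown, and 62 were also called lower in HSF123. Of the 409, 401 had a higher ratio in HSF123 than in HSF1 knockdown. The difference was at least 2-fold with a limma adjusted p under 0.05 for 108 of the 409. Without HSF1 replicate 1, 408 of the 409 were still called. The 409 probes formed 244 runs of consecutive numbers, so they may match fewer transcripts if consecutive probes share one. In the contrast, 111 of the 1747 were higher in HSF123 and 14 lower. Centring on the array median gave 384 lower in HSF1 and 45 in HSF123 knockdown, and quantile normalization, dim probes included, 479 and 12. Which genes these probes belong to was not analysed here.

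Ratios were more widely spread on each HSF1 array than on any HSF123 array. Over 10360 bright probes the SD of the log2 ratios within an array was 0.608 ± 0.00874 on the HSF1 and 0.458 ± 0.000955 on the HSF123 arrays (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow).

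A further 5609 probes above background in neither channel were called lower in HSF123 knockdown. A floor of the processed signal that differs between the dyes may explain these calls, as 27 control probes had a median ratio of −1.45. Lower transcript levels stay open: the set's median of −1.43 lay 0.0228 from that of the control probes, but choosing probes at the floor holds it there whatever the transcripts did.

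Probes with consecutive numbers changed alike, and one hypothesis is that they may match the same transcript. Over 12119 such pairs the difference between the knockdowns correlated at 0.804, against −0.0307 to 0.0238 in 100 shuffles and −0.0138 for numbers 50 apart. The 797 and 1306 probes that rose and fell in HSF1 knockdown formed 565 and 891 runs of consecutive numbers, and the 455 and 455 in HSF123 knockdown 292 and 323, so counts of probes overstate counts of transcripts if the hypothesis holds.

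The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For the contrast of the knockdowns, only 1 split, the real one, gave as many limma calls, both over all probes (1925) and above background (717), and the highest of the others was 0. At an unadjusted p under 0.05 and 2-fold, the other splits called up to 21 probes above background, and the real one 749. The other 3 splits that part all 3 slides also gave 0 adjusted calls. Each split other than the real one put arrays of both knockdowns on either side. The difference between the knockdowns then widened the spread within each side, so 0 calls there was close to fixed in advance. As the arrays are technical replicates, no split bears on differences between groups of males.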
